A study of Escherichia coli with 12 samples.

How the data were processed

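RNA from condensates and from total lysates of E. coli BL21(DE3) was sequenced for 2 constructs, M and MP. Per the labels, cells grew in 2xYT medium with 1% glucose, mCherry was induced with arabinose and Pum2-ELP-GFP with IPTG, and condensates were separated from the lysate on an OptiPrep density gradient at 37 C. RNA was extracted with TRIzol LS and made into libraries with the KAPA RNA HyperPrep kit and 10 cycles of PCR, per the labels' protocols. No depletion of rRNA is named in the labels. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these samples. Groups and replicate numbers were taken from the sample labels.

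Counts are whole-number reads per feature as deposited, not normalized, and per the file headers and names they came from Rockhopper, a tool for bacterial RNA-seq, whose version is not stated. The aligner settings and the genome build are not given in the sources used here. Rockhopper was run by the authors for condensates and for lysates separately, on the chromosome and on 1 plasmid reference. It called transcript ends in each run, so a feature can be counted over other ends in the 2 fractions. The authors' normalized counts, a score scaled per library and rounded to whole numbers per the file headers, served an alternative test only. The authors' deposited table of M against MP also gives a p-value and a q-value per feature from Rockhopper, per the file headers, and these are described without a test. The deposited feature lengths, in an other unit, bases, were over 15000 for 150 condensate and 137 lysate features, so lengths were computed from the deposited coordinates instead. Each library's counts were equal to the matching column of the whole-series table, and 0 columns could not be matched to a sample.

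The condensate tables hold 4400 features and 4397 stand in the lysate tables. Condensates and lysates were joined on 4306 common features, 4299 on the chromosome and 7 on the plasmids, of which 3709 had equal ends in both runs. Reads that map to several copies appear to be counted at each copy: the highest of the 7 copies of 16S rRNA and of 23S rRNA had at most 1.16 times the counts of the lowest in any library. The 8 genes of 5S rRNA, and the copies of lacI and araC on chromosome and plasmid, share sequence as well. Such genes are uncertain, and overlapping and antisense features are too, since the strand setting of the counting is not given in the sources used here. Rockhopper's features antisense to rRNA, 79 in condensates and 85 in lysates, and its predicted RNAs, 94 and 91, stayed in the library totals.

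All 12 libraries were compared with each other before any test. M lysate 3 and MP lysate 2 were equal in 100% of features, where other pairs were equal in 1.0% to 10.1%. They were counted as 1 library of unknown construct and left out of the fits, a departure from the design written before the data were examined, which used 12 libraries. The fits therefore hold 10 libraries. Using the shared library as deposited, as M alone or as MP alone are alternatives chosen after seeing the data.

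The tests were edgeR quasi-likelihood tests (version 4.0.16, R 4.3.3) on raw counts, with TMM scaling, filterByExpr and a Benjamini-Hochberg adjusted p under 0.05. MP was compared with M in the 6 condensates and in the 4 lysates, each fitted alone. Condensate against lysate within M, within MP and as their mean, and the interaction of construct and fraction, came from 1 fit of 4 group means over the 10 libraries. The residual degrees of freedom were 4, 2 and 6, and the biological coefficients of variation 28.8%, 35.8% and 28.3%. Log2 fold changes are edgeR's with its default prior count. A prior count of 2 was used only for log CPM values, as in the list tests. Levels of single genes are CPM on the TMM-scaled library size, and levels of mCherry are CPM on the plain library total. Shares and ratios were compared with two-sided exact permutation tests. Groups of 3 or fewer were too small for a test of outlying libraries.

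Gene lists, 34 in all, were fixed as patterns on gene symbols or product names before the data were examined. Those with at least 5 tested members were tested with camera (limma 3.58.1, preset correlation 0.01), again with an estimated correlation, and with fry. The product patterns for rRNA and tRNA also matched modifying enzymes, so both lists were restricted to the RNA features. Copies of these genes share reads, so their members are not independent and a preset correlation makes their camera p-values too small. The prophage pattern also matches phage shock products. The list of small regulatory and structural RNAs had fewer than 5 tested members and was not tested.

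The genes named follow a rule fixed at the same time. It takes every plasmid feature and every tested arabinose and lac gene. For each comparison and direction it takes the 10 genes with the largest log2 fold change among those with adjusted p under 0.05, a mean count of at least 50, a symbol and non-overlapping replicates (within both constructs for the mean), without rRNA and tRNA. For the interaction it takes 5 per direction. From each list described it takes the 4 tested members with the largest absolute log2 fold change.

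Alternatives were DESeq2 size factors, library totals, the DESeq2 Wald test (1.42.0), no filter on low counts, at least 50 counts in at least 3 libraries, rRNA and tRNA or plasmid features left out, the replicate number as a block, all libraries together or a construct alone, the authors' normalized values in limma with a pseudocount of 1, and each library left out in turn. Chosen after seeing the data were the uses of the shared library, features with equal ends only, an even background subtracted, protein-coding genes only, rRNA counted once and both condensates numbered 1 left out. The background was each library's median density of counts in the lowest 10% of genes of at least 300 bases with equal ends. For lysate libraries these were the genes lowest in condensates, and for condensate libraries those lowest in lysates. A planned test of native transcripts holding the Pum2 recognition motif was not run, because no genome sequence was used here.

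The replicate numbers come from the labels, which do not say what they mean. Deviations of M and MP condensates from their group means correlated at 0.67, 0.44 and 0.27 for numbers 1, 2 and 3 across 1654 genes, so the numbers were taken to pair the condensates, although M condensate 2 correlated more with MP condensate 3 (0.54) than with its own number. M condensate 3 and MP condensate 2 correlated at 0.14, so that number 1 alone stands apart. Condensates and lysates of the same number correlated at 0.12 and 0.17 in M and at −0.52 and −0.34 in MP and were not paired in the main fits. The replicate block across fractions and in the interaction did pair them by construct and number. There M condensate 3 and MP condensate 2 had no lysate partner and did not inform the contrast.

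The fits were tested on simulated counts with 200 changed genes and a dispersion of 0.08. Of 100 genes changed 2-fold and 100 changed 4-fold, 28% and 88% were recovered for MP against M in condensates (2952 genes), 16% and 84% in lysates (4138 genes) and 69% and 100% for the mean of condensate against lysate (3287 genes). False calls were 4.9%, 2.9% and 5.1% of calls. The lysate fit, with a biological coefficient of variation of 35.8%, varied more than this dispersion. Both simulated groups also shared the same mean profile, unlike condensates and lysates. These rates may therefore be too favourable for lysates and for condensate against lysate. Total counts were 35077318 to 47141642 per condensate library and 84831840 to 282849742 per lysate library compared. Few of them fall on chromosomal genes, which limits the precision for genes of low level. Correlations across genes used 100000 permutations. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used for joins, tests of single values and plots.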

Results

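RNA was sequenced from Escherichia coli BL21(DE3), a laboratory strain that makes T7 RNA polymerase when induced, carrying 2 plasmids. A pET plasmid encoded Pum2-ELP-GFP, a fusion of the RNA-binding protein Pum2 to an elastin-like polypeptide and green fluorescent protein that forms synthetic condensates in the cells. A pBAD plasmid encoded the red fluorescent protein mCherry, either alone (M) or with 5 copies of the Pum2 recognition sequence in the 3' untranslated region of its mRNA (MP). For each construct 3 libraries were deposited from condensates purified on a density gradient and 3 from total cell lysates, which gives 12 libraries in 4 groups. The design asks which RNAs the condensates hold and whether the recognition sequence changes them.

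M lysate 3 and MP lysate 2 held identical counts in all 4397 features. They were taken as 1 library deposited under both constructs, which leaves 11 distinct libraries, and because its construct could not be told it was left out of every fit. The lysate groups therefore held 2 libraries each, M lysate 1 and 2 and MP lysate 1 and 3, and 10 libraries were compared. Leaving out a lysate leaves its group with 1 library, which the fit then assumes to vary like the other groups. The labels do not say whether the libraries of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

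Total counts in the M condensates were 35737182, 35077318 and 38740192, and in the MP condensates 47141642, 39127814 and 37518723. The lysates were deeper, with 260528048 and 230260736 in M and 84831840 and 282849742 in MP. Most of these counts lay in ribosomal RNA or in the Pum2-ELP-GFP transcript. Chromosomal genes other than rRNA and tRNA received 885018 to 1634192 counts per condensate library and 515775 to 762556 per lysate library, with a median of 15 to 29 and 26 to 46 counts per feature. Fraction was the main difference between libraries, with 80.3% of the variance on the first principal component.

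The condensate libraries were rich in counts at the feature of their own scaffold mRNA and poor in rRNA. That gene is annotated at 11365 to 14007 of the plasmid reference. Its feature was counted over 7944 to 14214 in condensates and 6290 to 14215 in lysates, so it takes in upstream plasmid sequence. Pum2-ELP-GFP took 50.8% ± 5.6 of the counts in condensates (SD, n = 6) and 10.4% ± 6.4 in lysates (SD, n = 4), a difference with a two-sided exact permutation p of 0.0095, the smallest this design allows. Ribosomal RNA took 40.0% ± 6.3 in condensates and 87.5% ± 6.6 in lysates (n = 6 and 4, exact permutation p = 0.0095). Reads of the rRNA copies appear to be counted at each of them, and with each kind counted once the rRNA shares were 9.04% and 55.8%. The ratio of 23S to 16S counts, the large and small subunit rRNAs, was 0.694 ± 0.387 in condensates and 1.80 ± 0.080 in lysates (n = 6 and 4, exact permutation p = 0.0095). All plasmid features together held 54.3% ± 5.8 and 10.5% ± 6.4 of counts, or 84.4% and 41.7% with rRNA counted once. Set against chromosomal genes the direction turned, since Pum2-ELP-GFP gave 15.9 ± 2.61 counts per chromosomal gene count in condensates and 28.9 ± 9.08 in lysates (n = 6 and 4, exact permutation p = 0.0095), and plasmid features made up 94.3% and 96.4% of plasmid and chromosomal counts together.

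**Figure D1:**
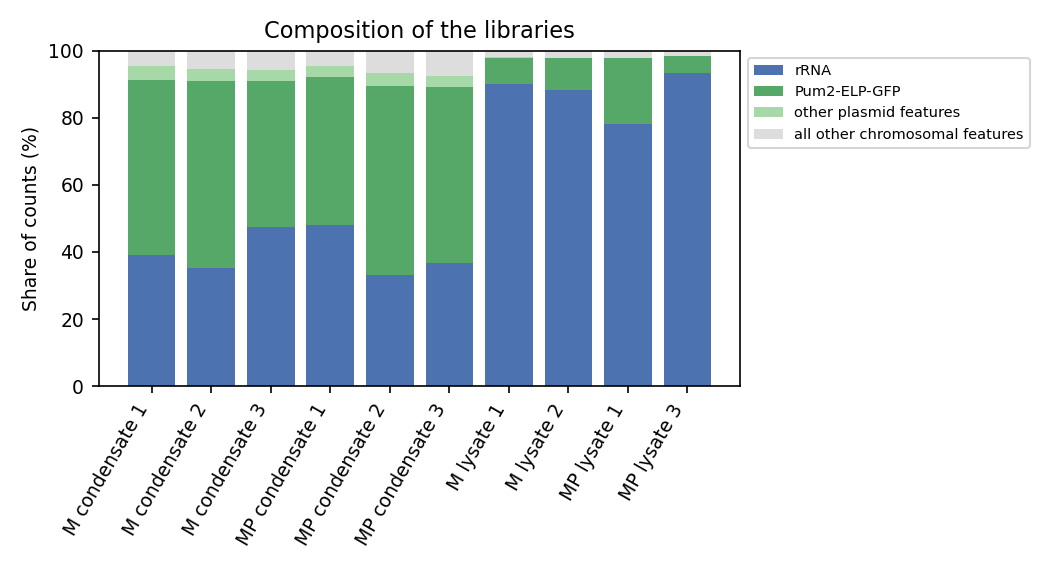
Share of counts (%, vertical axis) in each of the 10 libraries compared, split into rRNA counted at every copy, Pum2-ELP-GFP, other plasmid features and all other chromosomal features. Pum2-ELP-GFP holds 43.7% to 56.4% of counts in the 6 condensate libraries and 4.98% to 19.6% in the 4 lysate libraries.

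The mCherry transcript, the target of the recognition sequence, was counted more in MP condensates than in M condensates in every library. Its counts were 15182, 12879 and 8672 in M condensates and 29598, 32718 and 25609 in MP condensates, which is 338.6 ± 103 and 715.5 ± 108 CPM (counts scaled to the library total; SD, n = 3 each), a 2.11-fold difference. Relative to cat, the chloramphenicol resistance gene of the same plasmid, the levels were 396 ± 77.4 in M and 796 ± 113 in MP per 1000 cat counts, a 2.01-fold difference. Relative to Pum2-ELP-GFP counts the difference was 2.12-fold. The two-sided exact permutation tests of these measures each gave p = 0.1 with n = 3 per group, the smallest that 3 libraries against 3 can give. In the fit over all genes the log2 difference was 0.58 (SE 0.24), a fold of 1.49 with a 95% interval of 1.02 to 2.19. It did not pass the edgeR quasi-likelihood test after Benjamini-Hochberg adjustment over all genes (unadjusted p = 0.0414, adjusted p = 0.397). In lysates mCherry stood at 49.1 ± 15.1 CPM in M and 51.2 ± 28.3 in MP (n = 2 each), where an exact permutation test cannot go below 0.333. Per 1000 cat counts it stood at 1262 and 1175 in M and 529 and 1098 in MP, and per 1000 chromosomal gene counts at 19.4 and 21.5 in M and 7.92 and 13.0 in MP, so that both MP lysates lay below both M lysates on these scales. Relative to Pum2-ELP-GFP counts, or to the library total with rRNA counted once, the lysates overlapped, with MP at 0.873-fold and 0.866-fold of M. The fitted log2 difference was −0.73 (SE 0.68, edgeR adjusted p = 1.0), or 0.06 with library totals, and −1.30 without MP lysate 3 (edgeR adjusted p = 0.0272), where MP lysate 1 stands alone and is assumed to vary like the M lysates. The mapping reference named its mCherry feature as the form with recognition sites for both constructs. The gene is annotated at 4731 to 5624 of the plasmid reference and was counted over 4651 to 5854 in condensates and 4675 to 5874 in lysates.

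**Figure D2:**
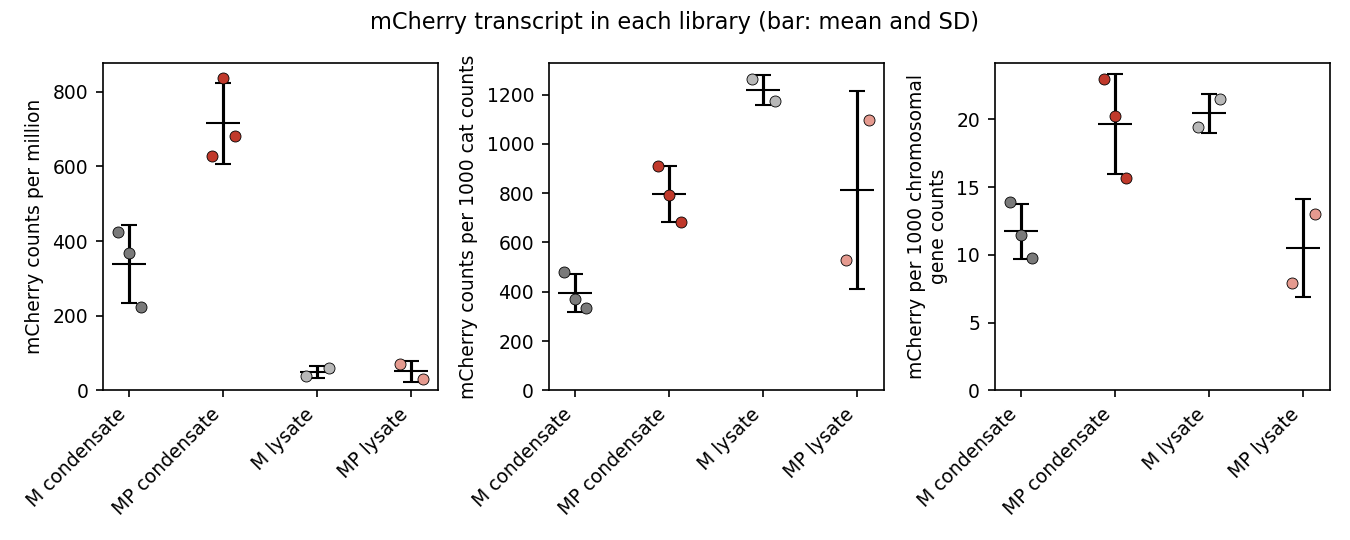
mCherry transcript per library (points) with the group mean and SD (bars), as CPM, per 1000 counts of cat and per 1000 chromosomal gene counts, for 3 libraries per condensate group and 2 per lysate group. The 3 MP condensates lie above the 3 M condensates on each scale, and the MP lysates lie apart from each other.

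Between the constructs, no single gene passed the main test in condensates. Among 2884 features, 0 passed an adjusted p of 0.05 in that edgeR quasi-likelihood test. The lowest adjusted p was 0.145, and 336 had an unadjusted p under 0.05. With the replicate number as a block 10 features passed, as described below. Some also passed without a block when all libraries were fitted together or when both condensates numbered 1 were left out. DESeq2, another count model, called 50, of which 45 were lower in MP. Of these 45, 44 were measured in both fractions and 34 were higher in condensates than in lysates (edgeR adjusted p under 0.05). The heat shock chaperones and proteases, which refold or degrade unfolded proteins, stood higher in MP as a list. Of its 18 members 17 had a positive log2 difference, with a median of 0.51, and clpB at 0.82 (SE 0.22), dnaK at 0.75 (SE 0.21), htpG at 0.73 (SE 0.17) and groL at 0.70 (SE 0.20) were farthest from 0. Of the 18, 0 passed over all genes and 6 passed higher when adjusted over the list alone. The list had a camera adjusted p of 1.3e-07, and an adjusted p = 0.428 with an estimated correlation. The 5 features that DESeq2 called higher in MP were clpB, dnaK, groL, htpG and macB, a subunit of a macrolide efflux pump.

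Other lists also passed between the condensates. Amino acid biosynthesis stood higher in MP (80 members, median 0.22, camera adjusted p = 0.0015; adjusted p = 0.428 with an estimated correlation), with hisH 0.81, thrC 0.77, hisB 0.76 and ilvD 0.74, genes of the histidine, threonine and branched-chain pathways. NADH dehydrogenase I, the first complex of the respiratory chain, stood higher in MP (9 members, median 0.73, adjusted p = 0.0047; adjusted p = 0.428 with an estimated correlation), with nuoF 1.38, nuoE 1.11, nuoC 1.00 and nuoB 0.75. Toxin-antitoxin pairs stood higher as well (13 members, median 0.35, adjusted p = 0.0072; adjusted p = 0.640 with an estimated correlation), with mqsA 0.66, hicA 0.53, yafQ −0.50 and mqsR 0.43. The tRNA list stood lower (29 members, median −1.04, adjusted p = 0.0015; adjusted p = 0.748 with an estimated correlation) and the asparagine tRNA genes asnU (−1.61), asnV (−1.60), asnT (−1.56) and asnW (−1.55) led. The rRNA list stood lower (22 members, median −0.51, adjusted p = 0.0023; adjusted p = 0.748 with an estimated correlation), and the 16S genes rrsD (−0.87), rrsH (−0.87), rrsA (−0.86) and rrsB (−0.86) led. No member of these 5 lists passed alone, over all genes or adjusted over the list alone. Copies share reads, so the preset tests of the tRNA and rRNA lists count some reads more than once. The condensate libraries numbered 1, in both constructs, held 21.3 and 17.7 tRNA counts per 1000 chromosomal gene counts against 0.764 to 2.21 in the other 4. The tRNA call ended without M condensate 1 (adjusted p = 0.395) or MP condensate 3 (0.130). The rRNA call ended without MP condensate 2 (adjusted p = 0.135) or 3 (0.0935), and the NADH dehydrogenase call without MP condensate 1 (0.0853) or without both condensates numbered 1 (0.0995).

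No plasmid, lac or arabinose gene passed the edgeR test over all genes between condensates. A short predicted plasmid RNA at 683 to 878 had a log2 difference MP against M of −2.10 (SE 0.40, edgeR adjusted p = 0.190 over all genes and 0.0109 adjusted over the plasmid features alone; DESeq2 adjusted p = 2.7e-06). Further log2 differences were −0.52 (SE 0.55, edgeR adjusted p = 0.755) for Pum2-ELP-GFP, −0.43 for cat, and −0.31 for the kanamycin resistance gene aph(3')-Ia. They were −0.43 for the plasmid copy of araC, the arabinose regulator, −0.38 for the plasmid copy of lacI, the lac repressor, and −0.77 for rop, which limits plasmid copy number. The lac genes lay at −0.97 for lacA, −0.66 for lacY, −0.42 for chromosomal lacI and −0.38 for lacZ, and the arabinose genes at 0.57 for araE, 0.42 for araH, −0.33 for chromosomal araC and −0.16 for araJ. Scaling by library totals moved all genes up by 0.54 log2 (median 0.00 to 0.54). It left mCherry at 1.08 and turned cat to 0.11, aph(3')-Ia to 0.23, plasmid araC to 0.14, plasmid lacI to 0.24, lacZ to 0.21, chromosomal lacI to 0.21, chromosomal araC to 0.21, araJ to 0.42 and Pum2-ELP-GFP to 0.01. With the replicate number as a block, which pairs these condensates, 10 features passed and all were lower in MP. The following, named after their values were seen, were among them: yjgL (log2 −1.60, edgeR adjusted p = 0.0080), yccE (−1.43, 0.0353), the Rhs-family gene rhsD (−1.33, 0.0416), wbbB (−2.08, 0.0430) and the plasmid RNA at 683 to 878 (−2.07, 0.0353). The ribosomal protein list, with a median of −0.49, did not pass without the block (camera adjusted p = 0.148; adjusted p = 0.807 with an estimated correlation). It passed lower in MP with the block (adjusted p = 0.012) and with library totals (adjusted p = 0.0024), where its median of 0.01 lay below the 0.54 of all genes. It also passed lower without M condensate 2 (adjusted p = 9.0e-04), M condensate 3 (0.0074) or MP condensate 1 (0.030), each with a preset correlation.

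In lysates, no single gene passed between MP and M either. Of 4043 features 0 passed the edgeR test (120 at an unadjusted p under 0.05). DESeq2 called 0 (50 unadjusted). The tRNA list stood lower in MP (69 members, median −1.19, camera adjusted p = 1.6e-28; adjusted p = 0.672 with an estimated correlation), with leuT (−2.77), leuV (−2.39), valV (−2.19) and valW (−2.09), genes of leucine and valine tRNAs, in front. It had 0 members lower over all genes and 4 lower when adjusted over the list alone. Copies of tRNA genes share reads, so the test with a preset correlation counts some reads more than once. Heat shock chaperones and proteases stood higher, with a median of 0.60 over 19 members (adjusted p = 3.5e-08; adjusted p = 0.672 with an estimated correlation) and clpP 1.07, clpB 0.94, ibpB 0.90 and clpA 0.83. Glycolysis and the phosphotransferase system stood higher (17 members, median 0.40, adjusted p = 0.0015; adjusted p = 0.672 with an estimated correlation), with the glucose transport component gene crr at 1.05, fbaB 0.62, ptsH 0.61 and pfkA 0.59. RpoS and stationary phase genes did too (24 members, median 0.27, adjusted p = 0.0023; adjusted p = 0.672 with an estimated correlation), with the DNA-protecting protein gene dps at 1.19, hdeD 1.00, osmY 0.98 and the acid resistance transporter gene gadC at −1.0. The lac operon list stood lower with TMM scaling and turned to 0.53 with library totals (5 members, median −0.58, adjusted p = 0.0147; adjusted p = 0.672 with an estimated correlation), with lacI −0.84, lacA −0.58, lacY −0.44 and lacZ −0.18. The other plasmid features lay at −0.56 (SE 2.33) for Pum2-ELP-GFP, −0.14 for cat, −0.57 for aph(3')-Ia, −0.13 for araC, −0.40 for lacI and −0.06 for rop, all positive with library totals. The arabinose list did not pass (camera adjusted p = 0.384), with araD −1.48, araJ 0.54, araH −0.42 and araA 0.32 farthest from 0.

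The lists of 4 further groups passed in lysates. Ribosomal proteins stood higher, with rpsT 1.48, rpmH 1.19, rplB 1.01 and rplL 0.97 (52 members, median 0.27, camera adjusted p = 2.7e-04; adjusted p = 0.672 with an estimated correlation). So did toxin-antitoxin pairs, with hicA 1.42, mqsA 0.87, mqsR 0.65 and yafO 0.62 (13 members, median 0.16, adjusted p = 0.0284; adjusted p = 0.672 with an estimated correlation). NADH dehydrogenase I stood higher with nuoM 0.68, nuoF 0.65, nuoE 0.56 and nuoG 0.49 (13 members, median 0.33, adjusted p = 0.0327; adjusted p = 0.684 with an estimated correlation). The rRNA list stood lower, with the 5S genes rrfD −0.95, rrfF −0.94, rrfA −0.92 and rrfE −0.92 (22 members, median −0.46, adjusted p = 2.7e-04; adjusted p = 0.678 with an estimated correlation). No member of the lists other than tRNA passed alone, over all genes or adjusted over the list alone. MP lysate 1 held 9.57 tRNA counts per 1000 chromosomal gene counts against 135 to 227 in the other 3 lysates. With library totals the median of all genes moved up by 1.15 log2, to 1.12. Relative to that median the heat shock list then stood at 0.39, RpoS at 0.30, glycolysis at 0.18, NADH dehydrogenase at 0.12, ribosomal proteins at 0.06, the lac operon at −0.59, rRNA at −1.24 and tRNA at −1.81. Each test that leaves out 1 of these 4 lysates sets a lone library, assumed to vary like the other group, against 2. Without MP lysate 1 the count of genes went from 0 to 127, the rRNA list turned higher (adjusted p = 0.0057) and the lac operon call ended (0.172). Without MP lysate 3 the count went to 154, and of these lists the rRNA and tRNA calls alone kept their direction and threshold, while that of heat shock ended (adjusted p = 0.107), as did those of ribosomal proteins (0.961), glycolysis (0.845), RpoS (0.0616), toxin-antitoxin pairs (0.593) and the lac operon (0.107), and NADH dehydrogenase turned lower (0.299). M lysate 1 decided RpoS (0.129), glycolysis (0.108), toxin-antitoxin pairs (0.504) and NADH dehydrogenase (0.108), and M lysate 2 the lac operon (0.165) and NADH dehydrogenase (0.165). Library totals ended the lac operon (0.195) and NADH dehydrogenase (0.0665) calls, and leaving out rRNA and tRNA those of NADH dehydrogenase (0.0569) and toxin-antitoxin pairs (0.0569). With the shared library used as deposited the call for toxin-antitoxin pairs ended (0.132).

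Condensates differed from lysates in most genes, in both constructs. Averaged over M and MP, 1047 features were higher and 1336 lower in condensates of 3247 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). In M 931 were higher and 1046 lower, and in MP 857 and 1058. The fold changes of both constructs had a Spearman correlation of 0.93 across genes, with 787 features higher in both, 866 lower in both and 0 called in opposite directions. Independent lists of these sizes would share 246 and 341. Both contrasts share the same runs, feature ends, scaling and fit, any of which can raise the overlap, so independence is no fair reference for it. These directions are relative to the bulk of genes under TMM scaling, where the median of all genes was −0.24. Scaling by library totals moved that median by 2.30 log2, to 2.05, and left 2163 higher and 30 lower (1931 and 19 in M, 1568 and 32 in MP). DESeq2 size factors moved the median by 0.12, leaving out plasmid features by 0.10 and leaving out rRNA and tRNA by 0.36. After an even background was subtracted from each library, 894 features were higher and 1091 lower, and among features counted over equal ends in both fractions 847 were higher and 916 lower.

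**Figure D3:**
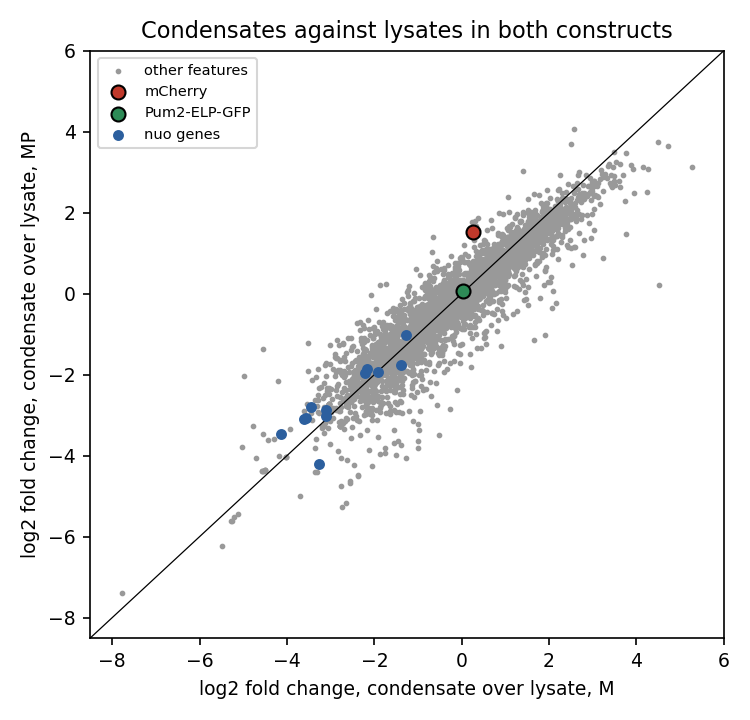
Log2 fold change of condensate over lysate in M (horizontal axis) and in MP (vertical axis) for each tested feature, TMM scaling, with mCherry, Pum2-ELP-GFP and the nuo genes of NADH dehydrogenase I marked and the line of equality drawn. Most features lie along the line (Spearman 0.93), mCherry lies above it, and the nuo genes lie low in both constructs, nuoG also under library totals (−1.31).

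Among the plasmid transcripts, mCherry was higher in condensates with TMM scaling, with a mean log2 fold change of 0.89 (SE 0.26, fold 1.85, edgeR adjusted p = 0.0085). This fold change was 1.51 (SE 0.38, fold 2.85, adjusted p = 0.0048) in MP and 0.26 (SE 0.36, adjusted p = 0.538) in M. The rise depended on the reference. Per 1000 chromosomal gene counts mCherry stood at 15.7 in condensates and 15.5 in lysates (n = 6 and 4, exact permutation p = 0.857). Per 1000 cat counts it stood lower in condensates, at 596 against 1016 (exact permutation p = 0.0857). Relative to Pum2-ELP-GFP counts it stood 1.95-fold higher (exact permutation p = 0.0381), and as CPM 10.5-fold. The resistance genes rose too, cat by 1.73 (SE 0.20, adjusted p = 1.4e-05) and aph(3')-Ia by 1.33 (SE 0.25, adjusted p = 5.2e-04), though both were counted over more bases in condensates (1204 against 803 for cat, 1082 against 878 for aph(3')-Ia). The plasmid copy of araC was lower, at −3.19 (SE 0.19, adjusted p = 1.2e-07), and rop was lower, at −1.37 (SE 0.33, adjusted p = 0.0028), though rop turned to 0.64 with library totals. Pum2-ELP-GFP itself, counted over 6271 bases in condensates and 7926 in lysates, stood at 0.05 (SE 0.47, adjusted p = 0.929) and plasmid lacI at 0.56 (SE 0.26, adjusted p = 0.069). Library totals placed them at 2.37 and 2.72, where all genes had a median of 2.05. The call for mCherry ended when only genes with at least 50 counts in at least 3 libraries were fitted (log2 0.37) or when an even background was subtracted (log2 0.37), with an edgeR adjusted p of up to 0.128 over its alternatives.

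Of single chromosomal genes, those highest in condensates by the fixed rule were ybl115 (log2 4.18, SE 0.17, 18.1-fold), ynhF, which encodes a small membrane protein (4.11, SE 0.22), yncM (3.67), ybfC (3.64), ymjA (3.62), the lambda prophage gene orf61 (3.53), psiF (3.50) and yfgI (3.48). They also took in msrB, a methionine sulfoxide reductase that repairs oxidised proteins (3.41), and yihF (3.39). Levels of ybl115 were 70.2 ± 28.5 CPM of TMM-scaled size in condensates (SD, n = 6) and 3.62 ± 0.163 in lysates (SD, n = 4), with no overlap between the fractions. By the same rule, the genes lowest in condensates were nuoG (−3.73, SE 0.34, 13.3-fold) and nuoC (−3.35, SE 0.29) of NADH dehydrogenase I. Plasmid araC (−3.19) and its chromosomal copy (−3.08), which share reads, were also among them. The others were epd (−3.15), the ribosomal protein gene rpmI (−3.01), recB of the RecBCD repair nuclease (−3.01), sucA of the citric acid cycle (−2.96), hflX, a ribosome-binding GTPase (−2.93), and rpoB of RNA polymerase (−2.91). Their edgeR adjusted p-values were at most 8.5e-06 among those higher and 2.0e-04 among those lower. The mean count per library was 116 to 3012 for the first 10 and 50.4 to 192 for the other 10. In condensates these lower genes had few counts, with mean levels of 0.140 (nuoG) to 0.673 (chromosomal araC) CPM of TMM-scaled size. In M condensate 3, nuoG stood at 0.042 CPM on a TMM-scaled size of 4.82e+07. The even background was estimated at 25.3% to 44.9% of the median gene density in the lysates. The folds of the lower genes were computed before its subtraction, so their size is uncertain. Of the 10 higher genes 3 (ybl115, ybfC and yihF) were counted over the same ends in both fractions, against all 10 of the lower ones.

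On the chromosome, ybl115 lies at 2625576 to 2626472, msrB at 1806387 to 1806800, nuoG at 2284685 to 2287411 and rpoB at 4089290 to 4093318, in the coordinates of the deposited tables for the BL21 chromosome, whose build is not given in the sources used here.

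Prophage and mobile element genes were higher in condensates as a group, with 122 of 200 members higher, 39 lower and a median log2 fold change of 0.87 (3.22 with library totals). The test against other genes gave a camera adjusted p of 4.3e-06, and an adjusted p = 0.622 with an estimated correlation. Adjusted over the list alone, 122 were higher and 40 lower, and the farthest were orf61 (3.53), yjhC (3.19), the integrase gene int_1 (3.17) and ea22 (2.99). Toxin-antitoxin pairs, which couple a growth inhibitor to its antidote, were higher in 9 of 13 members and lower in 0 (median 1.24, adjusted p = 0.0053; adjusted p = 0.622 with an estimated correlation), 9 and 0 when adjusted over the list alone. The leading members were hipA (2.09), hipB (2.03), yafN (1.87) and higA (1.87), and the call ended after an even background was subtracted (adjusted p = 0.063).

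NADH dehydrogenase I and the TCA cycle passed as lists, lower in condensates with TMM scaling. All 12 members of NADH dehydrogenase I fell, with a median of −3.03 (camera adjusted p = 9.3e-04; adjusted p = 0.622 with an estimated correlation; 12 lower adjusted over the list alone), which stayed negative with library totals at −0.54, and nuoF (−3.80), nuoG (−3.73), nuoC (−3.35) and nuoE (−3.32) led. In the TCA cycle 12 of 17 members were lower and 1 higher (median −1.16, adjusted p = 0.0260; adjusted p = 0.723 with an estimated correlation; the same counts adjusted over the list alone), with sucA (−2.96), sucB (−2.87), sdhA (−2.51) and mdh (−1.95, or 0.29 with library totals), and this median turned to 1.17 with library totals.

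Ribosomal proteins had 27 of 47 members lower and 6 higher (27 and 5 adjusted over the list alone), with a median of −1.61 that turned to 0.65 with library totals and rplV (−3.76), rpsS (−3.36), rpsH (−3.16) and rpmI (−3.01) leading (camera adjusted p = 0.0388; adjusted p = 0.772 with an estimated correlation). Aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, had 18 of 22 lower and 1 higher over all genes and adjusted over the list alone, with a median of −1.47 that turned to 0.83 with library totals (adjusted p = 9.1e-04; adjusted p = 0.622 with an estimated correlation), and metG (−2.48), aspS (−2.48), pheS (−2.41) and valS (−2.33, or 0.07 with library totals) led. RNA polymerase and its sigma and elongation factors had 12 of 15 lower and 2 higher, likewise adjusted over the list alone, with a median of −1.89 that turned to 0.44 with library totals (adjusted p = 0.0281; adjusted p = 0.755 with an estimated correlation), and rpoB (−2.91), nusA (−2.65), rpoC (−2.39) and nusB (−2.25, or 0.15 with library totals) led.

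All 22 rRNA genes fell (22 adjusted over the list alone), with a median of −3.03 that stayed negative, at −0.33, with library totals and the 23S genes rrlB (−4.48), rrlH (−4.48), rrlD (−4.47) and rrlA (−4.45) lowest (camera adjusted p = 4.5e-04; adjusted p = 0.766 with an estimated correlation). Of 53 tRNA genes 40 fell and 0 rose, over all genes and adjusted over the list alone, with a median of −3.08, or −0.48 with library totals, and glyU (−7.58), glyT (−5.86), asnV (−5.44) and asnU (−5.44), genes of glycine and asparagine tRNAs, lowest (adjusted p = 8.8e-05; adjusted p = 0.772 with an estimated correlation). Libraries overlapped, since MP lysate 1 held 9.57 tRNA counts per 1000 chromosomal gene counts and the condensates numbered 1 held 21.3 and 17.7. On that measure the fractions differed (0.764 to 21.3 in condensates and 9.57 to 227 in lysates, n = 6 and 4, exact permutation p = 0.0286), but not in the tRNA share of all counts (0.0217% and 0.0319%, exact permutation p = 0.2). The copies of these genes share reads, so single members are uncertain. The counts of members that fell and the camera tests with a preset correlation take the same reads in more than once.

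Cell division and cell wall genes had 26 of 35 members lower and 4 higher (27 and 4 adjusted over the list alone), with a median of −1.55 that turned to 0.88 with library totals (camera adjusted p = 4.1e-04; adjusted p = 0.622 with an estimated correlation), and the murein genes mrdA (−3.00), ddlB (−2.90), murE (−2.85) and murD (−2.84) led. The arabinose regulon had 6 of 7 members lower, likewise adjusted over the list alone, with a median of −1.86 that turned to 0.33 with library totals (adjusted p = 0.0379; adjusted p = 0.622 with an estimated correlation): chromosomal araC (−3.08), araG (−2.44), araA (−2.34), araJ (−1.86), araF (−1.65) and araE (−0.82), with araH at −0.55 and an edgeR adjusted p of 0.215. Amino acid biosynthesis had 52 of 87 lower and 19 higher, the same adjusted over the list alone, with a median of −0.85 that turned to 1.52 with library totals (adjusted p = 0.0260; adjusted p = 0.723 with an estimated correlation), with asd (−2.78), a gene of the aspartate pathway, ilvM (−2.62), serB (−2.55) and argA (−2.41) in front. Membrane proteins had 227 of 486 lower and 92 higher (227 and 91 adjusted over the list alone), with a median of −0.54 that turned to 1.72 with library totals (adjusted p = 0.0388; adjusted p = 0.622 with an estimated correlation), with ynhF (4.11), ampE (−3.59), yphE (−3.42) and ddpC (−3.35) farthest from 0. The lac operon did not pass as a list (camera adjusted p = 0.609, median 0.63), since lacZ was lower (−2.01, edgeR adjusted p = 3.4e-06; 0.42 with library totals) and lacA higher (1.90, 2.3e-06), with chromosomal lacI at 0.65 and lacY at 0.25.

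These list calls differed in how they stood up to other fits. None of the 13 held with an estimated correlation, and fry, which asks whether members move one way without comparing them with other genes, passed 25 lists (5 higher, 20 lower). Prophage genes, cell division, aminoacyl-tRNA synthetases and NADH dehydrogenase I held in the other settings run with camera and a preset correlation. Leaving out rRNA and tRNA ended the calls for ribosomal proteins (adjusted p = 0.150), RNA polymerase (0.118), TCA cycle (0.138) and amino acid biosynthesis (0.391), and using the shared library as deposited ended that for amino acid biosynthesis (0.104). Library totals ended those for TCA cycle (0.0815), amino acid biosynthesis (0.194) and membrane proteins (0.181). With equal ends alone the arabinose (0.0608), amino acid (0.0956) and membrane (0.485) calls ended, and with the background subtracted the arabinose (0.252) and membrane (0.430) calls. Without both condensates numbered 1 the TCA (0.053), arabinose (0.0591) and amino acid (0.109) calls ended. Leaving out MP lysate 3 ended the calls for ribosomal proteins (adjusted p = 0.352), RNA polymerase (0.132), TCA cycle (0.152) and amino acid biosynthesis (0.258). Leaving out M lysate 1 (0.138, 0.0621, 0.075, 0.183) or M lysate 2 (0.141, 0.104, 0.0897, 0.196) ended the same 4 calls. The call for ribosomal proteins also ended without M condensate 2 (0.080), M condensate 3 (0.0646) or MP condensate 3 (0.0544), and with the replicate block. Without MP lysate 1 the calls for the arabinose regulon and membrane proteins ended.

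**Figure D4:**
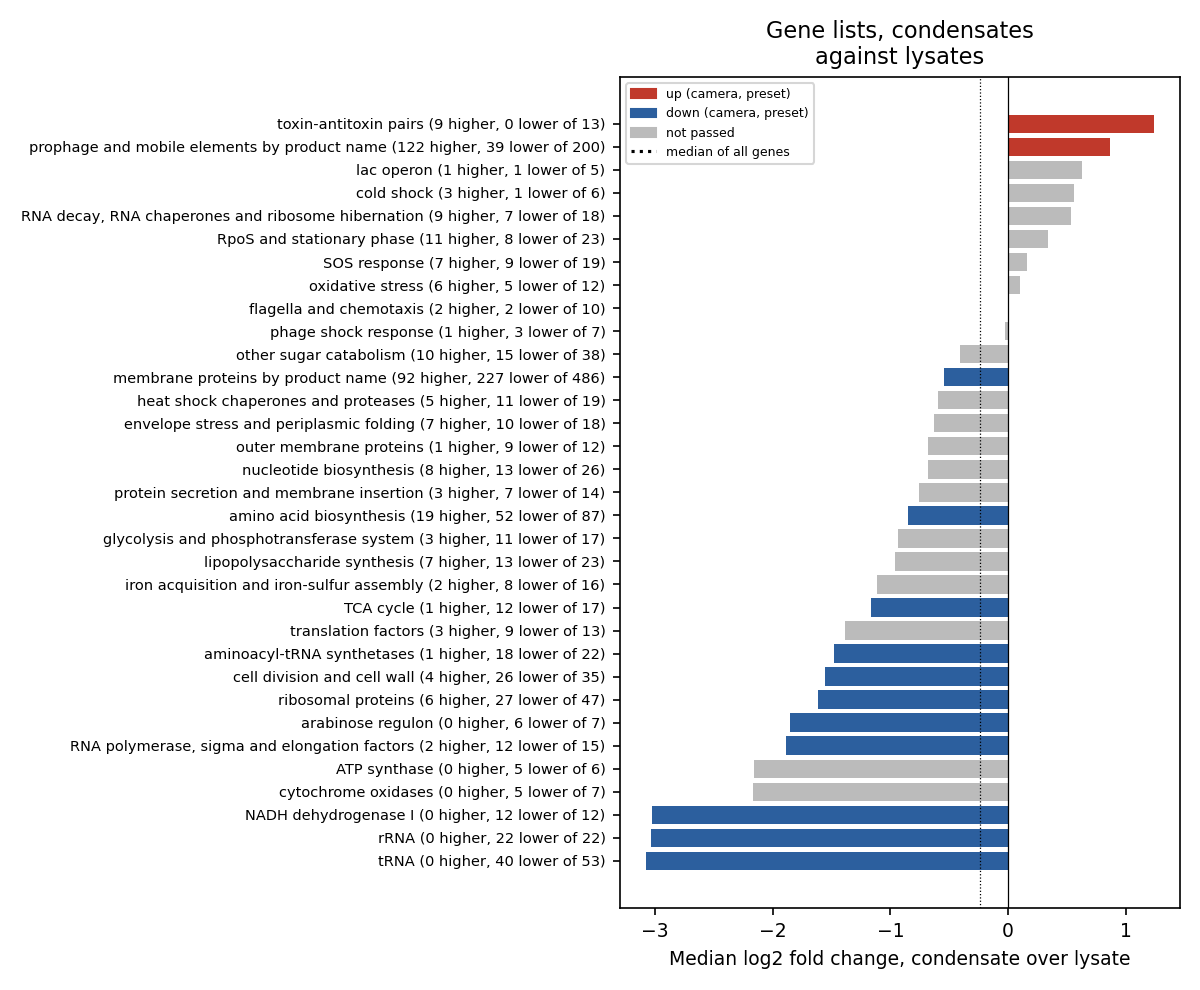
Median log2 fold change of condensate over lysate, mean of M and MP, for each gene list with at least 5 tested members under TMM scaling; colours mark lists past the camera test with a preset correlation, the dotted line marks the median of all genes (−0.24) and labels give members higher and lower. NADH dehydrogenase I, rRNA and tRNA lie lowest with this scaling and stayed negative with library totals, under which the other lower lists that passed turned positive; toxin-antitoxin pairs and prophage genes lie highest.

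The interaction of construct and fraction asks whether the recognition sequence changed what entered condensates over the lysate level. For mCherry the condensate over lysate ratio was 2.38-fold higher in MP than in M, a log2 difference of 1.25 (SE 0.51, 95% interval 0.15 to 2.36). The edgeR test gave an unadjusted p of 0.0296. This did not pass over all genes (adjusted p = 0.968) or adjusted over the plasmid features alone (adjusted p = 0.207). Without MP lysate 3 the difference was 1.94, and without MP lysate 1 it was 0.77. For Pum2-ELP-GFP the interaction was 0.02 (SE 0.93, edgeR adjusted p = 1.0). Among all genes 0 of 3247 passed the edgeR test, the lowest adjusted p was 0.465 and 163 had an unadjusted p under 0.05, while DESeq2 called 24, all lower in MP. Library totals moved the median of all genes in this contrast by −0.55. Ribosomal proteins stood lower in MP as a list, with a median of −0.98 (camera adjusted p = 5.0e-04; adjusted p = 0.923 with an estimated correlation) and rpsT (−4.33), rplA (−2.98), rplD (−2.81) and rpmH (−2.79) lowest. This call ended without M condensate 1 (adjusted p = 0.564) or MP lysate 3 (0.336). The cold shock list, the csp gene family and the helicase gene deaD, also stood lower (median −0.69, camera adjusted p = 0.0357, or 0.923 with an estimated correlation), with cspG −1.90, deaD −1.08, cspC −1.02 and cspD −0.36. It ended without M condensate 1 (0.204), M lysate 1 (0.363), MP lysate 1 (0.0539), MP condensate 2 (0.056) or MP lysate 3 (0.307), without both condensates numbered 1 (0.206), and with the shared library used as deposited (0.0579). The cell division list stood higher with a median of 0.22 that turned to −0.32 with library totals (adjusted p = 0.0201; adjusted p = 0.923 with an estimated correlation), with ftsW 0.87, ftsP −0.84, ddlB 0.81 and ftsL 0.77. It ended without M lysate 1 (0.238), M lysate 2 (0.0766), M condensate 3 (0.195), MP condensate 1 (0.149) or MP lysate 1 (0.264). It also ended with library totals (0.102), without rRNA and tRNA (0.0922), with equal ends alone (0.110), without both condensates numbered 1 (0.206) and with the replicate block (0.233). No member of the 3 lists passed, over all genes or adjusted over the list alone.

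Longer genes were lower in condensates. Across 3240 chromosomal genes the log2 fold change of condensate over lysate had a Spearman correlation with length of −0.37 and a Pearson correlation of −0.27 (permutation p = 1e-05 for Spearman, the smallest that 100000 permutations can give). The Spearman correlation was −0.29 among features with equal ends, and −0.23 with the background subtracted, where the Pearson correlation was −0.11. The genes named above ranged from 90 bases (ynhF) to 1431 (yihF) among those higher and from 198 (rpmI) to 4029 (rpoB) among those lower. Genes are not independent replicates of one another, so this p describes these genes.

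In the authors' deposited table of M against MP, 107 condensate features had a q-value under 0.05, of which 65 were genes and 36 were tRNAs, and 0 lysate features did, where 156 had a p-value under 0.05. The deposited lysate columns hold the shared library under both constructs, and whether the authors' lysate values were computed with it in both groups is not given in the sources used here. The table gives rop a q-value of 0.0144 and mCherry a q-value of 1 in condensates.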

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

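The tests of the mapping reference, of library scaling and of recruitment were chosen only after the mCherry values had been seen.

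The log2 ratio of MP to M for mCherry was 1.251 higher in condensates than in lysates (95% interval 0.15 to 2.36), with the 3 MP condensates above the 3 M condensates. The lysates overlapped as CPM on library totals, but per 1000 chromosomal gene counts both MP lysates (7.92 and 13.0) lay below both M lysates (19.4 and 21.5). They also overlapped relative to Pum2-ELP-GFP, so how much of this difference lies in the lysates depends on the reference (0.513-fold to 1.04-fold, MP over M). The edgeR test of that difference gave an unadjusted p of 0.00092 to 0.248 over 22 settings, under 0.05 in 11 of them, and did not pass after adjustment in any (adjusted p 0.119 to 1.0). Scaling as the whole cause is argued against, since the condensate difference stayed at 0.5643 or more in every setting with all libraries, and at 1.67-fold to 2.12-fold over 5 references (the library total, that total with rRNA counted once, cat, Pum2-ELP-GFP and chromosomal genes). A mapping reference that holds the recognition sites could add counts to mCherry in MP alone, but by the same factor in both fractions, so the interaction bears on it, and its highest p of 0.2476 leaves this open. Recruitment by the recognition sequence, the biological explanation the design names, predicts a positive interaction; 1.251 is positive without passing adjustment, so recruitment and the mapping reference cannot be told apart with 2 usable lysates per construct.

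Predicted RNAs outside the annotated features also had signal, given here as mean CPM in the condensates or lysates. The highest was 33310 for an RNA at 6562 to 7775 of the plasmid reference, antisense to aph(3')-Ia. It has no separate lysate feature, since the Pum2-ELP-GFP feature on the same strand runs from 6290 to 14215 there and covers it, and from 7944 to 14214 in condensates. A plasmid RNA at 683 to 878 had 232.6 in condensates. RNAs antisense to lacI had 4159 (336144 to 337082 of the chromosome) and 4160 (748687 to 749625) in condensates. In lysates they had 856.3 (336165 to 337067) and 857 (748702 to 749605). These copies share reads with each other and sequence with plasmid lacI at 9808 to 10890. The Pum2-ELP-GFP feature runs over plasmid lacI on the other strand in both runs. Whether these antisense reads came from that transcript was not tested. An RNA at 3957787 to 3957934 had 202.6 in condensates.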

How the results depend on the processing

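The uses of the shared library, equal ends, subtracted background, rRNA counted once and the libraries numbered 1 left out were chosen after seeing the data. Over all values and alternatives 374 kept direction and side of the threshold or moved little, 34 moved, 31 reversed, 6 grew past the threshold and 2 fell short of it. Where no reason is given, the cause was not tested. The mCherry difference between condensates stayed positive (0.4622 to 1.0794), and gene length stayed negative (−0.4235, to −0.2275 with the background subtracted).

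Genes past the threshold between condensates went from 0 to 50 with DESeq2, 10 with the replicate block, 6 with all libraries together and 30 without those numbered 1. In lysates they ranged from 0 to 154 with a library left out (127 without MP lysate 1, 154 without MP lysate 3), where a lone library is assumed to vary like the other groups, as in all fits without a lysate. Between fractions, fitting fewer genes gave 1311 (50 counts) and 1309 (equal ends) in M and 1517 (50 counts) for the mean. The interaction had 24 with DESeq2.

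Library totals gave Pum2-ELP-GFP 0.0119 between condensates, 0.5205 between lysates, 2.6197, 2.1189 and 2.3693 between fractions in M, MP and the mean, and −0.5008 in the interaction, and mCherry 0.0596 between lysates and 2.8432 between fractions in M. With at least 50 counts, mCherry was −0.3322 in M and 0.3671 in the mean, and Pum2-ELP-GFP −0.5499, −0.4398 and −0.4948. With the background subtracted they were 0.3724 and −0.4895 in the mean. With M alone they were −0.1254 and −0.3417.

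Pum2-ELP-GFP between fractions was −0.0163 in M with the block, 0.3477 in the mean with DESeq2, −0.0972 in MP as deposited, and −0.1285 in MP and −0.0301 in the mean with the shared library as MP. Its interaction was −0.0236 (DESeq2), −0.0685 (no filter), −0.0115 (rRNA and tRNA out), −0.2023 (as deposited), −0.1969 (shared library as MP) and −0.1374 (numbered 1 out). With 1 library left out, it ranged from −0.133 to 0.484 in MP (−0.0751 without MP condensate 1, −0.133 without MP lysate 1), from −0.0463 to 0.3807 in the mean (−0.0411 and −0.0463 without the same) and from −0.1734 to 0.2067 in the interaction (−0.007 and −0.0111 without M condensate 1 or 2, −0.1 and −0.0328 without M lysate 1 or 2, −0.068 without MP condensate 1, −0.1734 without MP lysate 1). mCherry between lysates ranged from −1.2977 (without MP lysate 3) to −0.3006, between fractions from 1.0346 to 2.4373 in MP and 0.6486 to 1.4654 in the mean, and in the interaction from 0.7722 to 1.944.

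Gene lists past the threshold fell to 0 with an estimated correlation in each comparison. With fry they were 0 for MP against M in condensates, 0 in lysates, 25 between fractions and 0 in the interaction. Without rRNA and tRNA they were 5 in lysates and 8 between fractions, and without those numbered 1 there was 1 in the interaction. With 1 library left out they were 2 to 15 in lysates (5 without M lysate 1, 15 without MP lysate 1, 2 without MP lysate 3) and 1 to 6 in the interaction (1 without M lysate 1, 6 without MP lysate 1, 5 without MP condensate 3 or MP lysate 3). Plasmid features were 94.33% of plasmid and chromosomal counts in condensates and 96.43% in lysates. With rRNA counted once they were 84.43% and 41.69%, and rRNA 9.044% and 55.82%.

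The replicate block changed no other count of genes by over 1.5 times. Across fractions it paired the condensate and lysate of the same construct and number, whose deviations correlated negatively in MP. With that pairing it ended the list calls for ribosomal proteins (camera adjusted p = 0.0663) and, in the interaction, cell division (0.233). In the interaction it also added rRNA, higher in MP (0.0467). That call used a preset correlation over gene copies that share reads. For MP against M in lysates no paired analysis was possible because these groups share only number 1. The motif test was not run. Depth limits genes of few counts, and the lysate comparison rests on 2 libraries a side.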

Other observations

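The tests of depth and of the recognition sequence for tRNA, and both tests of feature ends, were chosen only after the results had been seen.

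Several other lists held members that moved far in both directions between condensates and lysates and did not pass as lists (camera, preset correlation; edgeR counts are of members past an adjusted p under 0.05, and were the same adjusted over the list alone where not stated). Ribosome hibernation and RNA decay genes had 9 higher and 7 lower of 18 (median 0.54, adjusted p = 0.397), with the hibernation factor gene raiA at 3.09 and the ribonuclease genes rnc at −2.52, pnp at −2.51 and rne at −2.05 (0.18 with library totals). Heat shock genes had 5 higher and 11 lower of 19 (median −0.60, 1.77 with library totals, adjusted p = 0.280), with lon −2.62, dnaJ −2.45 and ftsH −2.29 against grpE 2.25, and passed lower with the background subtracted (0.0361). Envelope stress genes had 7 and 10 of 18 (median −0.63, 1.65 with library totals, 0.624), with bamA −2.90, cpxP 2.62, cpxR −2.53 and rpoE −2.12. Oxidative stress genes had 6 and 5 of 12 (median 0.10, mean −0.15, 0.834), with oxyR −2.60, sodB −2.39, soxS 2.26 and grxA 2.09. The SOS list had 7 and 9 of 19 (median 0.16, mean −0.02, 0.896), with uvrA −2.15 and dinI 2.04. RpoS genes had 11 and 8 of 23 (median 0.34, 0.269), with sra 2.63 and otsA −1.98. Cold shock genes had 3 and 1 of 6 (median 0.56, 0.624), with deaD −1.65. Nucleotide genes had 8 and 13 of 26 (median −0.68, 1.58 with library totals, 0.624), with pyrI 2.88, guaC 2.32 and carA −2.08. Lipopolysaccharide genes had 7 and 13 of 23 (median −0.96, 1.38 with library totals, 0.627), with rfaQ 3.05 and lpxC −2.48.

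Other lists leaned lower without passing, and their medians turned positive with library totals, which moved all genes by 2.30 log2. The passes under other settings named below used a preset correlation, and no list passed with an estimated one in the main fit. ATP synthase had 5 of 6 members lower (median −2.16, 0.04 with library totals, camera adjusted p = 0.0949), with atpF −3.01 and atpD −2.95, and passed lower with library totals (0.0042), without M condensate 1 (0.0448) and without both condensates numbered 1 (0.0130). Cytochrome oxidases had 5 of 7 lower (median −2.17, 0.38 with library totals, 0.083), with cyoD −2.78, and passed lower with library totals (0.0141), without MP condensate 1 (0.0420) and without both condensates numbered 1 (0.0293). Glycolysis had 11 lower and 3 higher of 17 (median −0.94, 1.52 with library totals, 0.169), with eno −2.32 and fbaB 2.21, and passed lower with the background subtracted (0.0133). Translation factors had 9 lower and 3 higher of 13 (median −1.39, 0.99 with library totals, 0.292), with fusA −2.59 and infA 2.07. Outer membrane proteins had 9 lower and 1 higher of 12 (median −0.68, 1.58 with library totals, 0.138), with ompA −2.42. Secretion had 7 lower and 3 higher of 14 (median −0.76, 1.58 with library totals, 0.441), with lepB −3.32 and ftsY 1.28. Iron genes had 8 lower and 2 higher of 16 (median −1.11, 1.03 with library totals, 0.157), with sufS −2.33, and passed lower without rRNA and tRNA (0.0050), without both condensates numbered 1 (0.0130), and without M lysate 1 (0.0065), M lysate 2 (0.0076) or MP lysate 3 (0.0054). Other sugar genes had 15 lower and 10 higher of 38, or 14 and 10 adjusted over the list alone (median −0.41, 1.82 with library totals, 0.627), with malP −2.22. Phage shock (median −0.02, 0.896) and flagella (median 0.00, 0.953; 2 higher and 2 lower of 10, or 2 and 1 adjusted over the list alone) lay near 0, with pspG 1.18 and tsr −3.29, and both turned positive under every other scaling.

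Genes lower in condensates could be lowered by an even background of reads in the lysates. It was taken from the genes lowest in condensates, whose lysate reads may also be real transcripts, so it was not measured apart from expression. After it was subtracted, 28.1% of the 1336 lower calls did not pass (190 tested and not past, 1 past in the other direction, 185 no longer tested), which leaves this open, since subtraction also removes counts. Genomic DNA as its source predicts more density near the replication origin: the Spearman correlation of lysate density with distance was −0.121 over 332 genes (permutation p = 0.0285), negative in 4 of 4 lysates, a small trend that does not settle it. Counting of the same genes over other ends is argued against, because 96.9% of the lower calls had equal ends in both runs, though features with other ends among the higher calls may shift the scaling. Of the 1047 higher calls only 53.1% had equal ends, and 491 of the 597 features with other ends were higher calls. The length of these 597 in condensates over lysates had a median log2 ratio of 0.057. Of the 491, 489 rose by more than their own length ratio. With equal-end features alone, 65.3% of 1295 such lower calls passed, and 556 of 556 higher ones. The biological explanation, that condensates hold less of these RNAs than the lysate, also stays open.

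More tRNA and 5S rRNA stood in the condensates numbered 1 of both constructs, at least 8.01-fold for tRNA per chromosomal gene count and 14.1-fold for 5S per 16S over the other 4 condensates. Genes under 300 bases less those over 1000 differed by −0.0858 log2 in MP and 0.0239 in M between these libraries and the others. Short protein-coding genes thus did not rise likewise. This cannot decide on recovery of short RNA, since the length used was that of the annotated gene and not of its RNA. Depth is argued against by its range of 1.344-fold, and the recognition sequence by a ratio of 1.208 between the M and MP libraries numbered 1. A step shared by the libraries numbered 1, such as an extraction that keeps more of the smallest structured RNAs, may remain; no label names one. No biological explanation was tested.

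For MP against M in condensates without the block, the real split gave 0 genes and the highest other split 0, and 10 splits are too few for a share under 0.05. With the block, 4 splits part all 3 same-numbered pairs, again too few; the real one gave 10 genes and the highest other 0. For the mean of condensate against lysate 1 of 100 splits, the real one, gave as many as 2383 genes. The highest of the others gave 229, setting condensates 2 and 3 of both constructs against the rest. That rest held all the lysates, so this split resembles the real contrast. Each of the other splits mixed condensates with lysates in a group, which widens the spread there and can lower the count. The share of 1 in 100 therefore cannot exclude chance.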
